A study of Mus musculus with 24 samples.

How the data were processed

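RNA was measured by bulk sequencing in 24 libraries of uteri from 21-day-old female mice. Per the labels' protocols, RNA was extracted with Trizol, cleaned on Zymo columns with DNase treatment, and made into TruSeq libraries. Progesterone was injected under the skin at 0.5 mg in 0.05 ml of sesame oil, and vehicle animals received oil alone, per the labels' protocols. Per the submitters' processing notes, cutadapt 2.7, TopHat and Partek were used with the build mm10. The counting tool, its annotation and strand setting, and the tool of the batch correction are not given in the sources used here.

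The authors deposited 1 table of gene-level RPKM (reads per kilobase of gene model, scaled to library size) after a batch correction, so its unit is neither plain RPKM nor counts. It holds 22943 genes, and 6.66% of its values lie below 0. The values show that the correction added 1 constant per gene to the libraries of a batch. The vehicle means of both batches were equal within a relative tolerance of 0.0001 for 13669 of 13669 genes with a mean above 1. Such a correction keeps differences within a batch on the RPKM scale and changes ratios, most in genes near 0. The design written before the table was opened assumed plain RPKM, and its test was kept with values below 0 set to 0. Among the tested genes 351 had a value below 0, which made up 0.297% of tested values.

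Values were tested as log2(RPKM + 0.5), which lowers the fold changes of low genes, while the constant of the correction and the setting of values below 0 to 0 can raise or lower them. A gene was tested with at least 1 RPKM in at least 4 libraries, which left 14284 genes. All 4 groups and a batch term were fitted in 1 limma model (limma 3.58.1, R 4.3.3, eBayes with trend and robust), with 19 residual degrees of freedom and a median of 3.34 prior ones. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05 over all tested genes. The contrasts were knockout against floxed after vehicle, knockout against floxed after progesterone, progesterone against vehicle in each genotype, and the difference of the last pair. Ctcf, Pgr and Esr1 were also compared with exact permutation tests. Gene coordinates are those of GENCODE M21 (GRCm38), which matched 21885 of the gene symbols.

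Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list moves on balance one way. Adjustment was over lists within a contrast. With an estimated correlation only beta protocadherins and p53 targets passed under vehicle, only beta protocadherins between genotypes after progesterone, only progesterone-responsive genes in each genotype's response, and no list for the difference in response. The lists were loop factors, beta, gamma and alpha protocadherins, Hox genes, imprinted genes, steroid receptors, progesterone-responsive and estrogen-responsive genes, hedgehog and WNT genes, gland, epithelium, squamous epithelium, stroma, smooth muscle, endothelium, leukocytes, mesothelium, ovary, oviduct, adipose tissue, skeletal muscle, nerve, red blood cells, cell cycle, p53 targets, interferon response, immediate early genes, clock genes and endometrial cancer genes. Some genes stand in more than 1 list. The score of a list in a library is the mean, over its tested genes, of the log2 value less that gene's mean over all libraries.

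The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from the alternatives the closing section names. The rule took, per contrast, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 RPKM in the higher group and a symbol that is not a predicted name. It added Ctcf, Pgr and Esr1, and up to 4 called members of each list with the smallest adjusted p. For the difference in response it took the 10 genes with the smallest adjusted p, and for a list with no called member, the 1 with the smallest p could be named. Ovgp1, Krt5, Xist and Kdm6a were chosen after their values were seen. Some genes that the rule names are not reported here. Named genes whose call rests on 1 library are given with the value without it.

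Depth was estimated from the steps between low values, since the table gives no counts. A single read's worth was read from at least 138 genes per library. Vehicle libraries numbered 1a and 1b, and 11a and 11b, differed as much as other pairs of libraries across batches and were kept as separate samples. The main fit used no block for replicate numbers, and whether these numbers pair samples is not settled.

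The fits were tested on simulated data in which a set of genes was changed by known amounts. Noise was normal and independent for each gene and library, with that gene's residual spread. Correlation between genes, outlying libraries, batch constants and values set to 0 were not simulated. The counts are therefore not error rates for the real data. In the simulation of the genotype effect under vehicle, 41 of 50 genes changed by 0.5 on the log2 scale were recovered, 45 of 50 by 1, 50 of 50 by 2 and 50 of 50 by 3, with 8 false calls among 14284 genes. In the simulation of the genotype effect after progesterone, 26 of 50 genes changed by 0.5 on the log2 scale were recovered, 44 of 50 by 1, 49 of 50 by 2 and 49 of 50 by 3, with 8 false calls among 14284 genes. In the simulation of the progesterone response in floxed controls, 22 of 50 genes changed by 0.5 on the log2 scale were recovered, 46 of 50 by 1, 48 of 50 by 2 and 50 of 50 by 3, with 10 false calls among 14284 genes. In the simulation of the progesterone response in knockouts, 27 of 50 genes changed by 0.5 on the log2 scale were recovered, 48 of 50 by 1, 48 of 50 by 2 and 50 of 50 by 3, with 11 false calls among 14284 genes. In the simulation of the genotype by progesterone interaction, 12 of 50 genes changed by 0.5 on the log2 scale were recovered, 39 of 50 by 1, 50 of 50 by 2 and 50 of 50 by 3, with 3 false calls among 14284 genes.

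Alternatives covered the pseudocount, the filter on low values, the batch term, each batch alone, the groups in the fit, median-ratio scaling, quantile normalization, the moderation of variances, weights per library, a block for replicate numbers, averaging of libraries with suffixes, and each library left out in turn. Count-based tests were not used, because the table holds no counts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for summaries, exact tests and figures.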

Results

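The data were gene-level RNA abundances of uteri from 21-day-old female C57BL/6 mice. In the knockouts a floxed Ctcf gene, which encodes a DNA-binding protein that organises chromatin loops, was deleted by a Cre recombinase expressed from the progesterone receptor gene Pgr. Controls were floxed littermates without Cre. Uteri were collected 6 hours after an injection of 0.5 mg of progesterone or of vehicle, sesame oil. The 24 libraries comprised 8 floxed and 8 knockout libraries after vehicle, and 4 floxed and 4 knockout libraries after progesterone. They came from 2 sequencing batches. The mixed batch held 4 libraries of each of the 4 groups, and the vehicle-only batch held the other 4 vehicle libraries of each genotype. Depth ranged from 29900000 to 100600000 reads per library, read from the value of a single read in genes with few reads. Its median was 49800000 reads in the vehicle-only batch and 72700000 reads in the mixed batch. Values are batch-corrected RPKM, and 14284 genes were tested. Errors of group means are SD and errors of log2 fold changes are SE. The labels do not state that each library came from a separate animal, so p-values measure only the spread between these samples.

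Some libraries carried markers of oviduct, squamous epithelium or fat. Ovgp1, an oviduct glycoprotein gene, reached 191 RPKM in knockout vehicle library 12, 379.8 RPKM in floxed progesterone library 7 and 146 RPKM in floxed vehicle library 3. In the vehicle-only batch it lay between 16.8 and 60.2 RPKM, values that include the constant of the authors' correction. Krt5, a keratin of squamous epithelium, was 50.5 RPKM in knockout vehicle library 9 and 14.8 RPKM in knockout progesterone library 8. Both are knockout libraries, and whether this signal came from tissue beside the uterus or from the uterus itself was not tested. Fat markers varied too. The list score of adipose tissue ran from −4 in floxed vehicle library 1a and −3.98 in floxed vehicle library 12 to 2.2 in knockout vehicle library 5, all of the vehicle-only batch, and from −0.678 to 1.74 in the mixed batch. These scores include the constant of the correction too, and values below 0 were set to 0 for them. A fat marker lay below 0 in libraries 1a and 12. How much of this range reflects fat in the samples was not tested.

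Ctcf RNA was lower in every knockout library than in any floxed library. Under vehicle it was 25.9 ± 2.36 RPKM (SD, n = 8) in floxed uteri and 11.4 ± 1.11 RPKM (SD, n = 8) in knockouts, with an exact two-sided permutation p of 0.000155, the smallest that 8 against 8 can give. After progesterone it was 26 ± 1.05 RPKM (SD, n = 4) and 9.95 ± 0.982 RPKM (SD, n = 4), with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 can give. Knockouts held 44.2% of the control level under vehicle and 38.3% after progesterone. Within batches the log2 fold change under vehicle was −1.08 in the mixed batch and −1.20 in the vehicle-only batch. The gene lies on chromosome 8 from 105636568 to 105682922 (GRCm38). Which part of it is removed is not given in the sources used here, and cells without Pgr-driven Cre are part of the tissue. Progesterone did not detectably change Ctcf in floxed uteri (log2 fold change 0.00 ± 0.09, adjusted p = 0.983) or in knockouts (−0.21 ± 0.09, adjusted p = 0.143), where an exact two-sided permutation test of Ctcf alone, unadjusted, gave p = 0.0444.

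**Figure D1:**
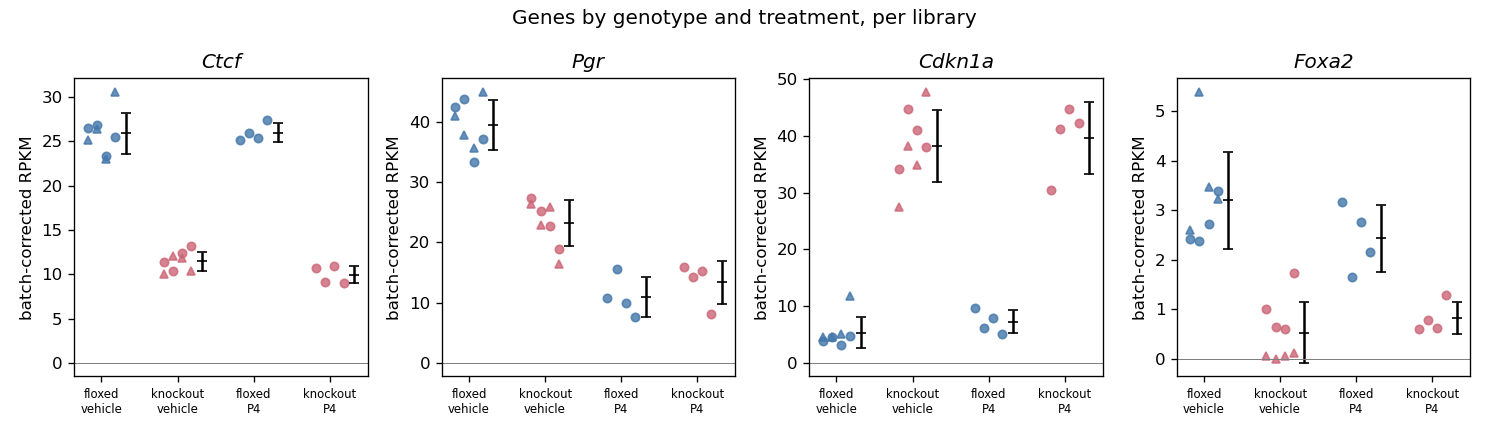
Batch-corrected RPKM (y axis) of Ctcf, Pgr, Cdkn1a and Foxa2 in each library of the 4 groups (x axis). Circles are the mixed batch, triangles the vehicle-only batch, and black bars are the mean ± SD. Ctcf was at least 23 RPKM in each floxed vehicle library and at most 13.1 RPKM in each knockout vehicle library.

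The first comparison asked which genes differed between knockout and floxed uteri without hormone. Beta protocadherins, cell adhesion genes in a tandem array, were lower in knockouts, as were Pgr, the hedgehog ligand gene Ihh and the gland regulator Foxa2. The cell cycle inhibitor Cdkn1a and other p53 targets were higher, as were many leukocyte markers. Of 14284 genes, 1878 were higher and 1638 lower in knockouts, and 443 of these 3516 differed by at least 2-fold. Under quantile normalization 1883 were higher and 2104 lower, a share of 47.2% higher against 53.4%. The mixed batch alone gave 2411 genes the vehicle-only batch alone 1085, the filter at 5 RPKM 2293 and weights per library 6500.

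All 19 tested beta protocadherins were lower, by log2 fold changes from −0.99 to −0.35 (camera adjusted p = 2.65e-20, and adjusted p = 0.003 with an estimated correlation), and 19 were lower adjusted over the list alone. They lie on chromosome 18 between 37300799 and 37524479. Pcdhb22 was 2.35 ± 0.278 RPKM in floxed and 0.934 ± 0.146 RPKM in knockout uteri (SD, n = 8 each), a log2 fold change of −0.99 ± 0.08, adjusted p = 6.16e-09. Pcdhb20 changed by −0.91 ± 0.08, adjusted p = 1.52e-08. Of 20 gamma protocadherins, between 37661793 and 37841873 on the same chromosome, 1 was higher and 16 were lower, and 1 was higher and 17 lower adjusted over the list alone (camera adjusted p = 1.91e-11, and adjusted p = 0.0843 with an estimated correlation). With quantile normalization none of them was higher and 17 were lower. Pcdhga1 changed by −0.81 ± 0.07, adjusted p = 2.54e-08. Members of each array have similar sequences and gamma genes share their last exons, so the split of reads among single members is uncertain. No alpha protocadherin passed the filter on low values.

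**Figure D2:**
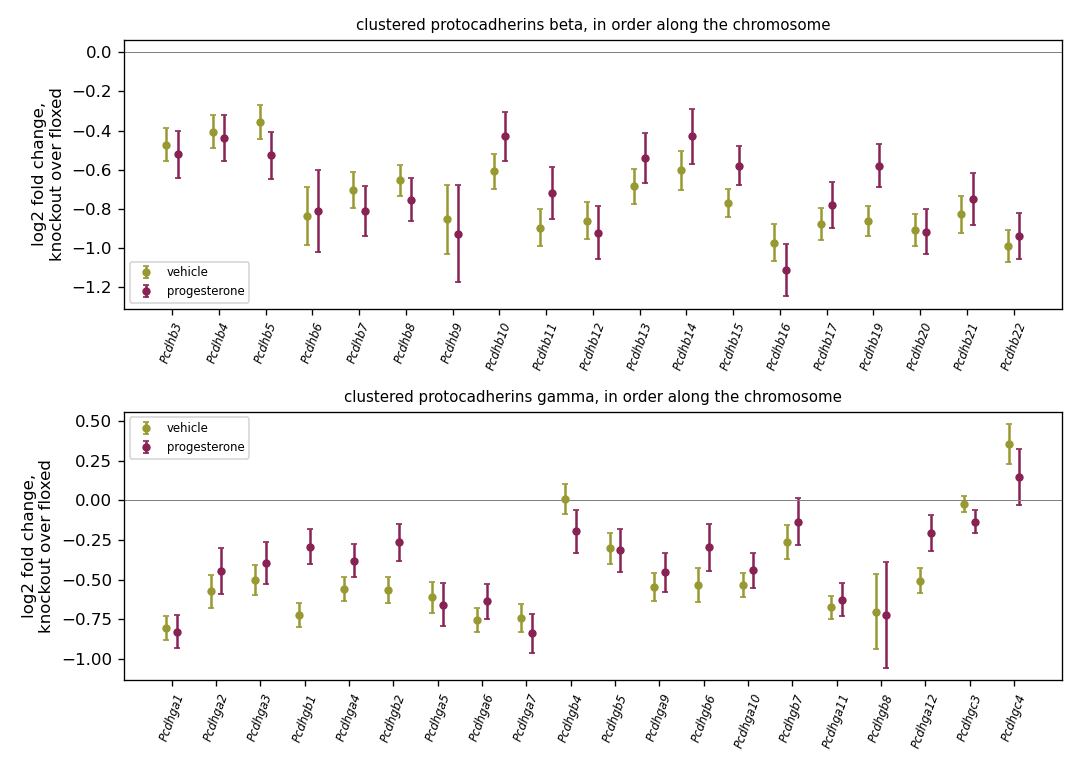
Log2 fold change of knockout over floxed uteri (y axis, bars are ± SE) for each tested beta (upper panel) and gamma (lower panel) protocadherin along chromosome 18, under vehicle and after progesterone. All 19 beta genes lie below 0 in both conditions, with values from −0.99 to −0.35 under vehicle.

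Hedgehog signalling carries signals from the uterine epithelium to the stroma. Of 13 hedgehog genes none were higher and 6 were lower, and 1 was higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00384, and adjusted p = 0.453 with an estimated correlation). Ihh was 10.2 ± 4.59 RPKM in floxed and 2.5 ± 1.46 RPKM in knockout uteri (SD, n = 8 each), a log2 fold change of −1.91 ± 0.28, adjusted p = 1.74e-05. The receptor gene Ptch1 changed by −1.33 ± 0.15, adjusted p = 5.44e-07. Pgr, on chromosome 9 from 8899833 to 8968611, was 39.5 ± 4.18 RPKM in floxed and 23.2 ± 3.84 RPKM in knockout uteri (SD, n = 8 each), a log2 fold change of −0.77 ± 0.14, adjusted p = 0.000235. The Cre of the knockouts is expressed from this same gene, and the controls lack it. Loss of Ctcf and presence of the Cre allele therefore cannot be told apart, for Pgr or for genes that respond to progesterone. The estrogen receptor gene Esr1 did not differ detectably (0.01 ± 0.05, adjusted p = 0.89). Of 25 genes known to respond to progesterone, 4 were higher and 9 lower, and 4 were higher and 11 lower adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.669 with an estimated correlation).

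Of 10 gland genes 3 were higher and 5 lower, and 3 were higher and 5 lower adjusted over the list alone, but the list did not pass by camera (camera adjusted p = 0.263). Foxa2, a transcription factor needed for uterine glands, was 3.2 ± 0.982 RPKM in floxed and 0.532 ± 0.61 RPKM in knockout uteri (SD, n = 8 each; log2 fold change −2.01 ± 0.24, adjusted p = 1.04e-06). Cxcl15, a chemokine gene of the glands, was 3.89 ± 0.95 and 0.402 ± 0.246 RPKM (log2 fold change −2.29 ± 0.19, adjusted p = 5.12e-09). Aldh1a1, a retinoic acid synthesis gene, differed in the other direction, by 1.11 ± 0.11, adjusted p = 4.11e-08.

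Of 22 p53 targets and apoptosis genes 14 were higher and 2 lower, and 18 were higher and 2 lower adjusted over the list alone (camera adjusted p = 3.1e-09, and adjusted p = 0.00658 with an estimated correlation). Cdkn1a was 5.31 ± 2.7 RPKM in floxed and 38.3 ± 6.36 RPKM in knockout uteri (SD, n = 8 each), a log2 fold change of 2.82 ± 0.18, adjusted p = 9.9e-11. The stress sensor gene Sesn2 and the cyclin gene Ccng1 changed by 1.48 ± 0.12, adjusted p = 5.38e-09 and 1.11 ± 0.10, adjusted p = 9.58e-09. Of 15 leukocyte markers 11 were higher and 1 was lower, and 12 were higher and 1 lower adjusted over the list alone (camera adjusted p = 4.93e-06, and adjusted p = 0.532 with an estimated correlation). The macrophage marker Cd68 changed by 1.20 ± 0.15, adjusted p = 1.72e-06 and the complement gene C1qb by 1.05 ± 0.15, adjusted p = 9.86e-06. Of 23 interferon-response genes 13 were higher and none lower, and 16 were higher and none lower adjusted over the list alone (camera adjusted p = 2.27e-05, and adjusted p = 0.669 with an estimated correlation). Usp18, which restrains interferon signalling, changed by 0.84 ± 0.21, adjusted p = 0.00447.

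Of 18 genes known to respond to estrogen 6 were higher and 2 lower, as they were adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.669 with an estimated correlation). That list gave a camera adjusted p = 0.107 without the 5 libraries that carried oviduct or squamous markers. Wnt7b, an epithelial WNT ligand gene, changed by 1.75 ± 0.18, adjusted p = 1.7e-07. Of 14 endothelial markers 5 were higher and none lower, and 7 were higher and none lower adjusted over the list alone (camera adjusted p = 0.00598, and adjusted p = 0.669 with an estimated correlation), with Egfl7 at 0.39 ± 0.07, adjusted p = 0.000153. Of 26 cell cycle genes 3 were higher and none lower, and none were higher and none lower adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.883 with an estimated correlation). The cell cycle list gave a camera adjusted p = 0.679 in the mixed batch alone and 0.237 without those 5 libraries, and all 3 calls were lost in each (log2 fold changes from 0.77 to 0.88, SE up to 0.58, against 1.02 to 1.09, SE up to 0.37 before, adjusted p from 0.295 to 0.341 in the mixed batch, and log2 fold changes from 0.86 to 0.88, SE up to 0.44, adjusted p from 0.129 to 0.194 without the 5). Of 6 skeletal muscle markers none were higher and 4 lower, and none were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00716, and adjusted p = 0.485 with an estimated correlation, and camera adjusted p = 0.125 in the mixed batch alone). They were listed as markers of tissue beside the uterus, and whether they report such tissue here was not tested.

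The 8 genes with the highest log2 fold changes were A2m, Igfbp2, Col6a5, Krt17, Egfl6, Ptgds, Cldn6 and Rec8. Igfbp2, which binds insulin-like growth factors, was 4.34 ± 1.88 RPKM in floxed and 78.6 ± 14.6 RPKM in knockout uteri (SD, n = 8 each; log2 fold change 4.12 ± 0.21, adjusted p = 6.66e-12). The imprinted growth factor gene Igf2 was 29.2 ± 12.6 and 111 ± 16.8 RPKM (log2 fold change 2.02 ± 0.19, adjusted p = 2.68e-08). The 8 lowest were Fxyd4, Slc13a5, Ggt6, Lrp2, Gkn3, Sult1d1, Adra2c and Ube2ql1. Fxyd4, a regulator of ion transport, was 82.6 ± 31.7 and 7.66 ± 6.18 RPKM, and Lrp2, an endocytic receptor gene, 13.1 ± 4.38 and 1.77 ± 1.86 RPKM. The authors' correction shifts each gene by a constant within a batch, which can change the fold change of a gene near 0. That of A2m, a protease inhibitor gene, was 4.55 over both, 7.10 in the mixed batch and 2.00 in the vehicle-only batch, and that of Egfl6 3.89, 1.88 in the mixed batch and 5.90 in the vehicle-only batch. Differences in RPKM, in which the constant cancels, varied between batches too. They were 115 RPKM in the mixed and 66.2 RPKM in the vehicle-only batch for A2m, and 18.9 and 32.9 RPKM for Egfl6. How far the correction accounts for the unlike fold changes was not tested.

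The second comparison asked which genes differed between genotypes 6 hours after progesterone. Fst, Cyp26a1 and Hsd11b2 were far lower in knockouts, and beta protocadherins were lower too. Wnt7b, the apoptosis gene Pmaip1 and many leukocyte markers were higher. In all, 1758 genes were higher and 1009 lower, a share of 63.5% higher. Under quantile normalization 52.7% of the called genes were higher. The mixed batch alone, which held all progesterone libraries, gave 3379 genes and weights per library 7123. A block for replicate numbers gave 822.

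Fst, on chromosome 13 from 114452290 to 114458951, encodes follistatin, an antagonist of activins. It was 27.9 ± 5.32 RPKM in floxed and 1.5 ± 0.233 RPKM in knockout uteri (SD, n = 4 each), a log2 fold change of −3.81 ± 0.25, adjusted p = 5.86e-10. Cyp26a1, which degrades retinoic acid, was 28.1 ± 9.41 and 2.37 ± 1.83 RPKM (log2 fold change −3.44 ± 0.38, adjusted p = 1.02e-06). Hsd11b2, which inactivates glucocorticoids, was 161 ± 20.4 and 27.6 ± 9.42 RPKM (log2 fold change −2.58 ± 0.25, adjusted p = 1.93e-07). The others of the 8 lowest were Tac2, Ttr, Acod1, Cxcl15 and Pate4. Of 25 genes known to respond to progesterone 3 were higher and 9 lower, and 3 were higher and 12 lower adjusted over the list alone (camera adjusted p = 3.01e-05, and adjusted p = 0.25 with an estimated correlation). The growth factor gene Areg, on chromosome 5 from 91139599 to 91148432, changed by −1.81 ± 0.15, adjusted p = 1.74e-08. Pgr was 11 ± 3.29 and 13.4 ± 3.6 RPKM and did not differ detectably (0.27 ± 0.20, adjusted p = 0.373). Esr1 differed by 0.21 ± 0.08, short of the threshold (adjusted p = 0.0555, and 0.0274 in the mixed batch alone), while an exact two-sided permutation test of Esr1 alone, unadjusted, gave p = 0.0286.

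All 19 beta protocadherins were lower, by log2 fold changes from −1.11 to −0.43 (camera adjusted p = 1.88e-17, and adjusted p = 0.00675 with an estimated correlation), and 19 were lower adjusted over the list alone. Pcdhb16 changed by −1.11 ± 0.13, adjusted p = 3.04e-06. Of 20 gamma protocadherins none were higher and 10 were lower, and none were higher and 11 lower adjusted over the list alone (camera adjusted p = 2.17e-08, and adjusted p = 0.215 with an estimated correlation), while with quantile normalization 15 were lower and 1 had the other sign. Of the 22 p53 targets 11 were higher and 1 was lower, and 14 were higher and 1 lower adjusted over the list alone (camera adjusted p = 3.87e-05, and adjusted p = 0.0939 with an estimated correlation). Pmaip1, a mediator of apoptosis, was 1.39 ± 0.577 RPKM in floxed and 8.94 ± 1.39 RPKM in knockout uteri (SD, n = 4 each; log2 fold change 2.36 ± 0.25, adjusted p = 5.07e-07). Of 15 leukocyte markers 10 were higher and none lower, and 13 were higher and none lower adjusted over the list alone (camera adjusted p = 4.76e-05, and adjusted p = 0.58 with an estimated correlation), with Fcer1g at 1.15 ± 0.24, adjusted p = 0.00149. Of 23 interferon-response genes 7 were higher and none lower, and 13 were higher and none lower adjusted over the list alone (camera adjusted p = 0.000113, and adjusted p = 0.722 with an estimated correlation), with Ifit2 at 0.73 ± 0.16, adjusted p = 0.00238. The knockout libraries were split on these 2 lists. Interferon scores were −0.583, −0.223, 1.02 and 0.389 in libraries 4, 5, 6 and 8, against −0.75 to −0.382 in floxed libraries, and leukocyte scores were −0.255, 0.42, 0.973 and 0.802, against −0.887 to −0.0017, so library 4 lay within the floxed range on both. Without library 6, 4 of the 7 interferon calls were lost (log2 fold changes from 0.46 to 0.68, SE up to 0.34, against 0.63 to 1.16, SE up to 0.40 before, adjusted p from 0.0757 to 0.18), and 3 without library 8 (log2 fold changes from 0.54 to 1.03, SE up to 0.43, against 0.63 to 1.16, SE up to 0.40 before, adjusted p from 0.0757 to 0.103). Of the 10 leukocyte calls 3 were lost without library 6 (log2 fold changes from 0.63 to 0.97, SE up to 0.40, against 0.77 to 1.14, SE up to 0.37 before, adjusted p from 0.0809 to 0.0999), 2 without library 5 (log2 fold changes from 0.81 to 1.11, SE up to 0.41, against 0.77 to 1.14, SE up to 0.37 before, adjusted p from 0.0695 to 0.0735) and 2 without library 8 (log2 fold changes from 0.61 to 0.96, SE up to 0.40, against 0.77 to 1.14, SE up to 0.37 before, adjusted p from 0.0974 to 0.137). Without library 4, 17 interferon and 13 leukocyte genes were called.

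Of 31 WNT and uterine patterning genes 13 were higher and 3 lower, and 15 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00884, and adjusted p = 0.58 with an estimated correlation). Wnt7b changed by 2.89 ± 0.26, adjusted p = 3.92e-08, and the WNT inhibitor genes Dkk2 and Notum by 1.31 ± 0.19, adjusted p = 3.7e-05 and 1.47 ± 0.24, adjusted p = 0.000127. Of 20 epithelial markers 7 were higher and none lower, and 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.722 with an estimated correlation). Cldn4, a tight junction gene, changed by 1.34 ± 0.20, adjusted p = 4.24e-05. Knockout library 8, with a Krt5 level of 14.8 RPKM, is 1 of the 4 knockout libraries here, and without the 5 libraries the epithelial list gave a camera adjusted p = 0.000389. Of 20 stromal and matrix genes none were higher and 3 were lower, and none were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00742, and adjusted p = 0.58 with an estimated correlation), with Pdgfra at −0.88 ± 0.15, adjusted p = 0.000197. Of 13 hedgehog genes none were higher and 3 were lower, and none were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00742, and adjusted p = 0.512 with an estimated correlation), with Gli3 at −0.65 ± 0.15, adjusted p = 0.00254. The 8 highest log2 fold changes belonged to A2m, Klk10, Krt17, Rec8, Mmp7, Dio2, Mal2 and Alox15. Klk10, a secreted protease gene, changed by 4.75 ± 0.34, adjusted p = 1.98e-09. The floxed mean of A2m, Krt17, Rec8 and Mmp7 lay below 0 after the authors' correction, so no fold is given for them.

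The third comparison described the response to progesterone in floxed controls. Progesterone raised Areg, Fst, Cyp26a1 and other known targets within 6 hours. It lowered Pgr, Esr1 and several WNT genes. Of 3280 genes that changed, 1120 rose and 2160 fell, a share of 34.1% higher. That share was 47.9% with median-ratio scaling and 46.5% with quantile normalization. The mixed batch alone gave 3741 genes, 1924 were called without the 3 libraries that carried oviduct markers, 2064 without all 5 and 6276 with weights per library.

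Of 25 genes known to respond to progesterone 13 rose and none fell, and 15 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.12e-12, and adjusted p = 0.0476 with an estimated correlation). Areg changed by 3.84 ± 0.14, adjusted p = 2.31e-14. Fst went from 4.04 ± 0.967 RPKM (SD, n = 8) to 27.9 ± 5.32 RPKM (SD, n = 4), a log2 fold change of 2.60 ± 0.24, adjusted p = 6.87e-08. Il13ra2, a decoy receptor of interleukin 13, changed by 3.58 ± 0.31, adjusted p = 3.56e-08 and Cyp26a1 by 3.90 ± 0.36, adjusted p = 7.29e-08. The amino acid transporter gene Slc6a14 had the highest log2 fold change, 4.33 ± 0.30, adjusted p = 1.62e-09, from 1.04 ± 0.841 to 29.2 ± 8.82 RPKM. The others of the 8 highest were Hsd11b2, Tac2, Spink8 and Ms4a8a. The 8 lowest were Dio2, Gabrp, Slc13a5, Cdh10, Gjb2, Lrrc55, Slc26a7 and Slc40a1. Slc40a1, the iron exporter gene, changed by −2.05 ± 0.21, adjusted p = 2.46e-07, and Dio2, which activates thyroid hormone, by −4.15 ± 0.45, adjusted p = 9.01e-07.

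Of 14 steroid receptors and cofactors 1 rose and 5 fell, as they did adjusted over the list alone (camera adjusted p = 0.0345, and adjusted p = 0.74 with an estimated correlation, and camera adjusted p = 0.128 in the mixed batch alone). Pgr went from 39.5 ± 4.18 to 11 ± 3.29 RPKM (log2 fold change −1.84 ± 0.18, adjusted p = 2.09e-07) and Esr1 from 49.7 ± 2.91 to 29.7 ± 1.56 RPKM (−0.74 ± 0.07, adjusted p = 1.65e-07). The glucocorticoid receptor gene Nr3c1 changed by −0.88 ± 0.10, adjusted p = 2.08e-06. Of 31 WNT and patterning genes 2 rose and 10 fell, and 2 rose and 14 fell adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.74 with an estimated correlation, and camera adjusted p = 0.0646 in the mixed batch alone). Wnt5a changed by −0.73 ± 0.06, adjusted p = 3.56e-08 and Wnt7a by −1.71 ± 0.23, adjusted p = 9.84e-06. Hoxa11 and Hoxa10, homeobox genes of the uterine stroma, changed by 0.90 ± 0.12, adjusted p = 1.32e-05 and 0.56 ± 0.10, adjusted p = 0.000225. Of 15 clock genes 2 rose and none fell, as they did adjusted over the list alone (camera adjusted p = 0.0425, and adjusted p = 0.74 with an estimated correlation, and camera adjusted p = 0.0563 in the mixed batch alone), with Npas2 at 1.32 ± 0.33, adjusted p = 0.00532.

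Of 19 beta protocadherins none rose and 9 fell after progesterone in floxed uteri, and none rose and 12 fell adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.74 with an estimated correlation), while with quantile normalization none rose and 1 fell, and 2 had the other sign. Of 20 gamma protocadherins none rose and 10 fell, as they did adjusted over the list alone (camera adjusted p = 0.00316, and adjusted p = 0.74 with an estimated correlation), while with quantile normalization none rose and 2 fell, and 7 had the other sign. Pcdhga12 changed by −0.66 ± 0.10, adjusted p = 9.21e-05. Floxed progesterone library 7, with an Ovgp1 level of 379.8 RPKM, is 1 of the 4 behind these values.

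The fourth comparison described the response to progesterone in knockouts. Slc6a14, Il13ra2 and Areg rose here, as did Ihh and the tight junction genes Cldn3 and Cldn4. Esr1 fell. Of 1238 genes that changed, 572 rose and 666 fell, a share of 46.2% higher. With median-ratio scaling 655 rose and 593 fell (52.5% higher), and with quantile normalization 755 rose and 659 fell (53.4% higher). The mixed batch alone gave 1229 genes. Without knockout vehicle library 9 and knockout progesterone library 8, which carried squamous markers, 687 were called, and without all 5 libraries 398. The count was 678 with only the groups compared in the fit, 1909 without a batch term and 5965 with weights per library, which did not converge fully. It was 162 with a block for replicate numbers.

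Of 25 genes known to respond to progesterone 13 rose and none fell, and 16 rose and none fell adjusted over the list alone (camera adjusted p = 2.1e-14, and adjusted p = 0.0247 with an estimated correlation). Slc6a14 changed by 3.79 ± 0.30, adjusted p = 1.82e-07, Il13ra2 by 3.16 ± 0.31, adjusted p = 9.31e-07 and Areg by 1.49 ± 0.14, adjusted p = 8.44e-07. Fkbp5, a cochaperone of steroid receptors, changed by 1.78 ± 0.35, adjusted p = 0.00244. Ihh went from 2.5 ± 1.46 RPKM (SD, n = 8) to 13.8 ± 2.32 RPKM (SD, n = 4), a log2 fold change of 2.14 ± 0.36, adjusted p = 0.000701. Its pathway's transcription factor gene Gli1 changed by 0.90 ± 0.17, adjusted p = 0.00174, and by 0.81 ± 0.23, adjusted p = 0.0703, without the 5 libraries. Of 13 hedgehog genes 3 rose and 2 fell, and 5 rose and 3 fell adjusted over the list alone, but the list did not pass by camera (camera adjusted p = 0.298). Pgr went from 23.2 ± 3.84 to 13.4 ± 3.6 RPKM (−0.81 ± 0.18, adjusted p = 0.00738), and the change was −0.53 ± 0.17, adjusted p = 0.0889, without the squamous-marker libraries. Esr1 changed by −0.54 ± 0.07, adjusted p = 6.41e-05.

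Of 20 epithelial markers 6 rose and none fell, and 10 rose and none fell adjusted over the list alone (camera adjusted p = 1.26e-07, and adjusted p = 0.54 with an estimated correlation). Cldn4 changed by 1.22 ± 0.19, adjusted p = 0.000266 and Cldn3 by 1.12 ± 0.19, adjusted p = 0.000601. Among 20 stromal and matrix genes 3 rose and 6 fell, and 3 rose and 9 fell with quantile normalization. Krt5 was 14.8 RPKM in progesterone library 8 and 50.5 RPKM in vehicle library 9 of this comparison. Of 6 mesothelial markers none rose and 1 fell, and none rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.54 with an estimated correlation), with Gpm6a at −1.12 ± 0.21, adjusted p = 0.00163. Their median log2 fold change was −0.78 in knockouts and −0.70 in floxed uteri, where 3 fell. All 3 of those calls were lost when 1 single library was left out (adjusted p from 0.065 to 0.13). Of 20 smooth muscle genes none rose and 2 fell, and none rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.769 with an estimated correlation), with the gap junction gene Gja1 at −0.74 ± 0.15, adjusted p = 0.0031. Without the 5 libraries the smooth muscle list gave a camera adjusted p = 0.11. Of 27 imprinted genes none rose and 5 fell, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.624 with an estimated correlation, and camera adjusted p = 0.268 in the mixed batch alone), with Peg10 at −1.10 ± 0.20, adjusted p = 0.00101 and Igf2r at −0.55 ± 0.11, adjusted p = 0.00238. In floxed uteri 1 imprinted gene rose and 6 fell over all genes, with a median log2 fold change of −0.15, against −0.12 in knockouts. Of 26 cell cycle genes none rose and 3 fell, as they did adjusted over the list alone (camera adjusted p = 0.0292, and adjusted p = 0.775 with an estimated correlation, and camera adjusted p = 0.147 in the mixed batch alone). All 3 calls were lost in the mixed batch alone (log2 fold changes from −1.15 to −0.67, SE up to 0.44, against −1.35 to −0.81, SE up to 0.41 before, adjusted p from 0.11 to 0.124) and when any of 14 single libraries was left out (log2 fold changes from −1.41 to −0.69, adjusted p from 0.0508 to 0.136).

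Of 19 beta protocadherins none rose and 3 fell, and none rose and 9 fell adjusted over the list alone (camera adjusted p = 5.84e-06, and adjusted p = 0.294 with an estimated correlation), while with quantile normalization none rose and 1 fell, and 0 had the other sign. Without knockout progesterone library 8, whose list score of −0.675 for beta genes was the lowest of all libraries, 2 of these 3 calls were lost (log2 fold changes from −0.32 to −0.27, SE up to 0.11, against −0.37 to −0.36, SE up to 0.11 before, adjusted p from 0.104 to 0.158), and without the 5 libraries all 3 were (log2 fold changes from −0.45 to −0.26, SE up to 0.14, against −0.54 to −0.36, SE up to 0.13 before, adjusted p from 0.103 to 0.38). Of 20 gamma protocadherins none rose and 4 fell, and none rose and 5 fell adjusted over the list alone (camera adjusted p = 0.000731, and adjusted p = 0.617 with an estimated correlation, and camera adjusted p = 0.127 without the 5 libraries), while with quantile normalization none rose and 1 fell, and 1 had the other sign. All 4 gamma calls were lost without library 8 (log2 fold changes from −0.40 to −0.24, SE up to 0.14, against −0.43 to −0.26, SE up to 0.13 before, adjusted p from 0.0555 to 0.133), which had the lowest gamma score, −0.524, and a slope of log2 values on transcript length of −0.193 per doubling. With that slope as a covariate 3 of the 4 were lost (log2 fold changes from −0.40 to −0.28, SE up to 0.14, against −0.43 to −0.34, SE up to 0.13 before, adjusted p from 0.0627 to 0.0743). The 15 clock genes had a median log2 fold change of 0.38, with none called by limma over all genes or adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0198, and adjusted p = 0.624 with an estimated correlation). The others of the 8 highest log2 fold changes were Fxyd4, Lrp2, Acbd7, Npl, Insl6 and Slc5a5, and the 8 lowest were Inhbb, Gabrp, Sprr1a, Cdh10, Lum, Slc26a7, Dio2 and Slc34a2. Lum, a matrix proteoglycan gene of the stroma, changed by −1.91 ± 0.31, adjusted p = 0.000512. Single libraries decided the calls of 3 of the 8 lowest. That of Slc34a2 was lost without knockout progesterone library 5 (−1.66 ± 0.42 before, then −1.56 ± 0.47, adjusted p = 0.0504). That of Dio2 (−1.67 ± 0.45) was lost without knockout progesterone library 4 (−1.60 ± 0.51, 0.0574) or 6 (−1.61 ± 0.51, 0.0547), or knockout vehicle library 9 (−1.37 ± 0.43, 0.0632) or 10 (−1.49 ± 0.47, 0.0509). That of Sprr1a (−2.18 ± 0.68, adjusted p = 0.0476) was lost when any of 15 single libraries was left out, with log2 fold changes from −2.32 to −1.59 and adjusted p from 0.0503 to 0.133, and in the mixed batch alone (−2.58 ± 0.78, 0.0526).

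**Figure D3:**
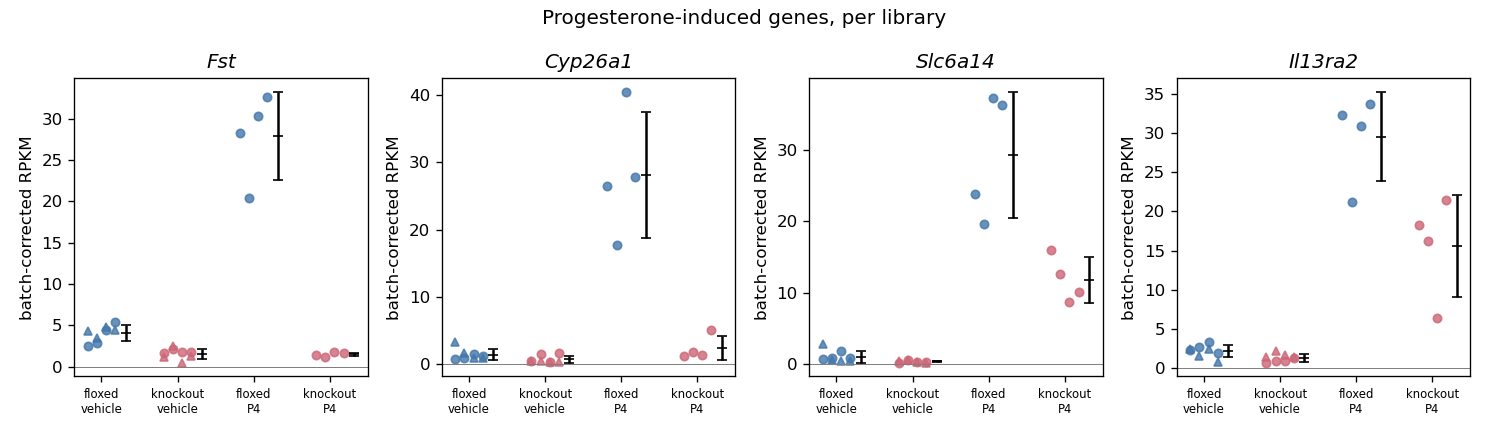
Batch-corrected RPKM (y axis) of Fst, Cyp26a1, Slc6a14 and Il13ra2 in each library of the 4 groups (x axis). Circles are the mixed batch, triangles the vehicle-only batch, and black bars are the mean ± SD. Fst averaged 27.9 RPKM in floxed and 1.5 RPKM in knockout uteri after progesterone.

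The fifth comparison tested whether the response to progesterone differed between genotypes, as a difference of the knockout response minus the floxed response. It did for 355 genes. As in each comparison of genotypes, loss of Ctcf and presence of the Cre allele cannot be told apart here. Areg, Fst, Cyp26a1 and the calcitonin gene Calca were induced less in knockouts. Of the 355 genes, 252 were called for progesterone in floxed uteri alone, 34 in knockouts alone, 56 in both and 13 in neither. Knockouts had the weaker response for 307 of the 308 called in floxed uteri, and floxed uteri had it for 45 of the 90 called in knockouts (84 of 121 in the mixed batch alone and 22 of 38 without the 5 libraries). Genes called in a genotype tend to respond more in it by selection, so neither share measures which genotype responds less. The mixed batch alone gave 421 genes, weights per library 4122, and 213 were called without the 5 libraries. A block for replicate numbers, which left 7 residual degrees of freedom, gave 26.

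The difference was −2.35 ± 0.19, adjusted p = 9.23e-08 for Areg, −2.67 ± 0.31, adjusted p = 2.32e-05 for Fst, −2.75 ± 0.47, adjusted p = 0.00135 for Cyp26a1 and −1.63 ± 0.24, adjusted p = 0.000386 for Calca. Fst was 1.6 ± 0.611 RPKM (SD, n = 8) in knockouts after vehicle and 1.5 ± 0.233 RPKM (SD, n = 4) after progesterone. The 10 genes with the smallest adjusted p were Tac2, Areg, Pate4, Raet1e, Pacsin3, Ripor2, Minar1, Tnni1, Fst and Pknox2. Tac2, which encodes neurokinin B, was 5.16 ± 0.609 RPKM in floxed and 0.353 ± 0.176 RPKM in knockout uteri after progesterone (SD, n = 4 each), with a difference in response of −2.62 ± 0.19, adjusted p = 1.87e-08. Pacsin3 differed in the other direction, by 1.12 ± 0.12, adjusted p = 1.17e-05. For Pgr the difference was 1.04 ± 0.24, adjusted p = 0.0197, from a lower vehicle level in knockouts. That call was lost in the mixed batch alone (1.00 ± 0.30, adjusted p = 0.087), without knockout progesterone library 5 (0.99 ± 0.26, 0.0571) and without floxed progesterone library 9 (0.89 ± 0.24, 0.062). Wnt5a had a difference of 0.51 ± 0.08, adjusted p = 0.000835 and Thy1, a stromal surface gene, of 0.56 ± 0.10, adjusted p = 0.00314.

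Of 20 epithelial markers 3 had a positive difference and none a negative one, and 14 had a positive one and none a negative one adjusted over the list alone (camera adjusted p = 8.9e-11, and adjusted p = 0.916 with an estimated correlation), with Ovol2 at 1.18 ± 0.24, adjusted p = 0.00595. Camera also passed, with its adjusted p in parentheses, for WNT genes (0.00107, 3 positive and none negative, and 5 positive and none negative adjusted over the list alone), stroma (0.0321, 1 positive and 1 negative, and 1 positive and 1 negative adjusted over the list alone), smooth muscle (0.0321), progesterone-responsive genes (0.0373), oviduct markers (0.0373) and cell cycle genes (0.0477). With an estimated correlation the adjusted p was 0.916 for each of these 7 lists. In the mixed batch alone camera did not pass for stroma (0.0662), progesterone-responsive genes (0.0864) or cell cycle genes (0.619), and the last gave 0.234 without the 5 libraries. No smooth muscle, oviduct or cell cycle gene was called alone by limma, over all genes or adjusted over the list alone, and 1, 1 and 0 of them had an unadjusted p under 0.05. The list score of oviduct markers was 3.27 in floxed progesterone library 7, against −1.18 to −1.13 in the rest of its group, and 2.996 in knockout vehicle library 12, and without the 5 libraries the list gave a camera adjusted p = 0.877. Adjusted over the list alone, 3 progesterone-responsive genes had a positive and 5 a negative difference, against 1 and 4 over all genes, and the median difference of that list, −0.02, was 0.01 with quantile normalization. Leaving out knockout progesterone library 5 gave 210 genes and leaving out floxed vehicle library 12 gave 716. The adipose score of library 12 was −3.98, but leaving out floxed vehicle library 1a, with a score of −4, gave 351 genes. With adipose, oviduct and squamous scores as covariates 463 genes were called, and the adipose list had a median difference of −0.97 (camera adjusted p = 0.0954).

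Among the 3280 genes called in floxed uteri, 2890 (88.1%) had the same sign in knockouts. The slope of the knockout on the floxed log2 fold changes across these genes was 0.486, and 0.445 in the mixed batch alone. With the 1238 genes picked on the knockout response, the slope of the floxed on the knockout changes was 0.899, and 0.786 in the mixed batch alone. Genes picked on a response tend to show a smaller response elsewhere, so the choice lowers each slope, and genes are not independent replicates. Both genotypes shared 359 genes that rose, where independent lists would share 44.9, and 478 that fell, where they would share 101.

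**Figure D4:**
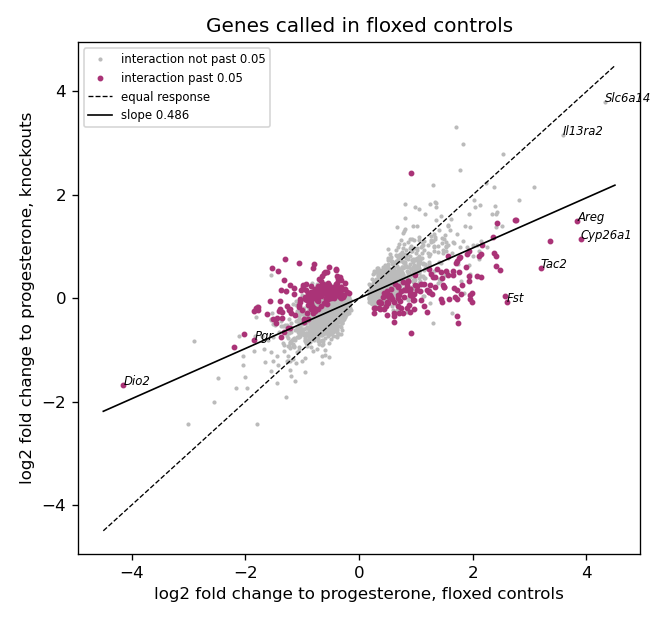
Log2 fold change to progesterone in knockouts (y axis) against floxed controls (x axis) for the 3280 genes called in floxed controls, each point a gene. Coloured points passed the test of a different response, the dashed line is an equal response and the solid line is the slope of 0.486 through 0.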

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

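The tests of libraries with oviduct or squamous markers, of calls on the RPKM scale among genes with a value below 0, of knockout vehicle library 9 and of permuted residuals were chosen only after their results were seen. Other splits of the samples were planned.

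Fewer genes were called for progesterone in knockouts (1238) than in floxed uteri (3280). The gap remained without the 5 libraries with oviduct or squamous markers, where 398 genes against 2064 were called. That does not settle whether these libraries account for it. Leaving them out took more libraries from knockouts than from floxed uteri, and the authors' correction was made with them included. With 300 genes picked in part of the floxed libraries, the knockout response was a median of 0.712 of the response in held-out floxed libraries over 12 splits, with a range from 0.452 to 0.926. With genes picked in part of the knockout libraries, the floxed response was 0.993 of the held-out knockout response, from 0.844 to 1.12. The choice of genes bears on such ratios and not on the counts, which cover all tested genes. The first median lies under the bound set for it beforehand, although the highest of the 12 splits passes that bound. The second median lies below 1, the least that the prediction of a weaker response required. A weaker response in knockouts may therefore underlie the counts as a hypothesis and is left open.

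Under vehicle 121 genes with a value below 0 were called between genotypes. The authors' additive correction could be the source of such calls on the log scale, while on the RPKM scale it cancels within a batch. In a least squares fit of genotype and batch on RPKM, 106 of these genes were also called with the same sign, and 15 were not (adjusted p up to 0.258). That share of 87.6% lies under the 90% set as the bound against it, so the correction stays open as a source of part of these calls and of the size of their fold changes. None of the 121 genes had the other sign in that fit. A limma fit on the linear scale kept 3267 of all 3516 genes called under vehicle, so some calls were lost with the scale among all genes too.

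Knockout vehicle library 9 had an Xist value of −4.54 RPKM, against 49.3 to 110.3 RPKM in the other 23 libraries. A swap with a floxed library is excluded by its Ctcf level of 11.4 RPKM, below every floxed library. Of 5 genes that escape X inactivation, 4 were lowest in it among the knockout vehicle libraries (Kdm6a was 9.06 RPKM, against at least 10.1), so a single X chromosome is a candidate explanation. Of 7 squamous markers, 5 were highest in it, so squamous tissue in the sample is a candidate explanation for those markers, and both can hold at once. Squamous tissue was not tested as a source of the Xist value. Knockout progesterone library 8, which carried squamous markers too, had an Xist value of 49.3 RPKM. Y-linked genes were not analysed here.

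Other splits of the samples into groups of the same sizes tested the counts against chance. For the genotype effect under vehicle 1 of 100 splits reached 3516 genes, the real one, and the highest other gave 1517. After progesterone it was 1 of 35, all that are possible (2767 genes, highest other 282). Both argue against chance among these libraries. In floxed uteri too only the real split reached its count (1 of 100, 3280 genes, highest other 1551), as in knockouts (1 of 100, 1238 genes, highest other 361). Splits for these responses moved labels across batches, while all real progesterone libraries were in the mixed batch, so they do not exclude chance there. The 100 splits were drawn from 6435 possible ones under vehicle and from 495 for each response. For the difference in response 6 of 100 regroupings gave as many as the real 355 genes, with a highest other of 2074. These regroupings reassign genotype within each treatment and batch, which carries genotype effects into the difference, a structure of the samples that lets some call several times the real count, so they do not decide on chance. When only residuals of a model without the difference were permuted, 1 of 100 reached 355, the real one, with a highest other of 318. That argues against chance on top of additive effects. The test was chosen after its result was seen, so chance is not excluded for this count.

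Single libraries stood far from the rest of their group for 49 of 460 groups over the 115 genes printed, 10.7%. Chance gives about 1 in 20, but Ovgp1, Krt5 and Xist were chosen after their values were seen and other genes for extreme changes, so the share is no test against it. In floxed vehicle library 1a, Cldn3 was 150 RPKM (others 65.2 to 93.3), Cldn4 was 28.3 RPKM (others 12.9 to 19.5), Cyp26a1 was 3.21 RPKM (others 0.806 to 1.56), Ggt6 was 16 RPKM (others 5.43 to 8.04), Ovol2 was 2.97 RPKM (others 1.4 to 1.97), Sult1d1 was 40.2 RPKM (others 6.23 to 20.9) and Wnt11 was 17.6 RPKM (others 5.71 to 9.68). The values in floxed vehicle library 12 stood apart where Cdkn1a was 11.8 RPKM (others 3.2 to 5.16), Egfl7 was 33.9 RPKM (others 36.8 to 38.8), Pcdhga1 was 1.91 RPKM (others 1.47 to 1.63), Pdgfra was 25.4 RPKM (others 36.1 to 42.8), Pknox2 was 15.3 RPKM (others 10.3 to 11.3) and Ripor2 was 2.91 RPKM (others 1.04 to 1.82). In knockout progesterone library 8, Cyp26a1 was 5.1 RPKM (others 1.25 to 1.76), Krt5 was 14.8 RPKM (others −4.28 to −1.63), Lum was 41.4 RPKM (others 10.1 to 15.2), Slc26a7 was −0.295 RPKM (others 1.29 to 1.41) and Ttr was 0.203 RPKM (others 0.0858 to 0.105). The values in knockout vehicle library 9 stood apart where Inhbb was 14.6 RPKM (others 1.35 to 5.9), Krt5 was 50.5 RPKM (others −1.92 to 10.1), Lum was 131 RPKM (others 45.3 to 82.3), Sprr1a was 21 RPKM (others 0.608 to 9.11) and Xist was −4.54 RPKM (others 64.1 to 110.3). In floxed progesterone library 7, Gabrp was 1.98 RPKM (others −0.89 to −0.842), Mmp7 was −0.784 RPKM (others −1.68 to −1.62), Ovgp1 was 379.8 RPKM (others −10.7 to 0.156), Slc34a2 was 2.24 RPKM (others −0.338 to −0.196) and Wnt7b was 0.602 RPKM (others 0.0259 to 0.119). The values in floxed progesterone library 1 stood apart where Calca was 3.29 RPKM (others 1.79 to 1.94), Gli1 was 65.2 RPKM (others 51.5 to 52.4) and Hoxd3 was 12 RPKM (others 9.34 to 9.61). In floxed vehicle library 7, Cyp11a1 was 0.333 RPKM (others 0.179 to 0.245), Foxa2 was 5.39 RPKM (others 2.38 to 3.48) and Gabrp was 10.3 RPKM (others 3.45 to 5.88). The values in knockout vehicle library 10 stood apart where Klk10 was 64.5 RPKM (others 16.3 to 37) and Mmp7 was 23.2 RPKM (others 4.08 to 9.99). In knockout vehicle library 13, Cxcl15 was 0.952 RPKM (others 0.186 to 0.515) and Raet1e was 0.759 RPKM (others 0.159 to 0.426). The values in floxed progesterone library 9 stood apart where Pdgfra was 52.4 RPKM (others 40.4 to 42.4) and Slc5a5 was 2.66 RPKM (others 0.595 to 0.872). In floxed vehicle library 3, Acbd7 was 0.943 RPKM (others 0.112 to 0.488) and Ovgp1 was 146 RPKM (others −12.3 to 60.2). The values in knockout progesterone library 6 stood apart where Tac2 was 0.092 RPKM (others 0.404 to 0.465). In knockout vehicle library 11a, Gli3 was 8.00 RPKM (others 5.62 to 6.72). The values in knockout vehicle library 12 stood apart where Ovgp1 was 191 RPKM (others −13.3 to 44.1). In knockout vehicle library 4, Slc5a5 was 1.64 RPKM (others 0.577 to 0.876). The values in knockout vehicle library 5 stood apart where Ttr was 0.309 RPKM (others −0.051 to 0.0854). In floxed vehicle library 10, Gkn3 was 19.9 RPKM (others 5.08 to 12). The values in floxed vehicle library 4 stood apart where Ptch1 was 39.5 RPKM (others 23.2 to 30.2).

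Among measures of whole libraries, the sum of RPKM was 311200 in knockout progesterone library 8 (others 254700 to 261200), the number of values below 0 was 1532 in floxed progesterone library 7 (others 2050 to 2073), the slope of log2 values on transcript length per doubling was −0.193 in knockout progesterone library 8 (others −0.0118 to 0.0227), the slope of log2 values on transcript length per doubling was −0.065 in knockout vehicle library 13 (others 0.0006 to 0.034), the mean log2 score of oviduct and ciliated cells markers was 3.27 in floxed progesterone library 7 (others −1.18 to −1.13) and the mean log2 score of basal or squamous epithelium markers was 1.33 in knockout progesterone library 8 (others −0.715 to −0.532). The response to progesterone differed between genotypes, by the test of the difference, for Tac2 (−2.62), Areg (−2.35), Pate4 (−2.52), Raet1e (2.38), Pacsin3 (1.12), Ripor2 (−1.93), Minar1 (−1.48), Tnni1 (2.24), Fst (−2.67), Pknox2 (−1.10), Pgr (1.04), Calca (−1.63), Cyp26a1 (−2.75), Gli3 (−0.83), Ptch1 (1.15), Wnt5a (0.51), Dkk2 (1.00), Ttr (−1.21), Ovol2 (1.18), Thy1 (0.56) and Sesn2 (−1.10), given as knockout minus floxed log2 fold change. The call of Gli3 (−0.83 ± 0.18) was lost in the mixed batch alone (−0.81 ± 0.21, 0.0519) or without the 5 libraries (−0.71 ± 0.18, 0.0681), with the difference there ± SE and its adjusted p in parentheses. The call of Ptch1 (1.15 ± 0.26) was lost without knockout progesterone library 5 (1.03 ± 0.27, 0.0577) or without the oviduct-bearing libraries (1.15 ± 0.30, 0.0503). The call of Dkk2 (1.00 ± 0.24) was lost without knockout progesterone library 4 (0.92 ± 0.25, 0.0508), without knockout progesterone library 8 (0.88 ± 0.24, 0.0561), in the mixed batch alone (0.94 ± 0.30, 0.114) or without the squamous-marker libraries (0.90 ± 0.25, 0.0642). The call of Ttr (−1.21 ± 0.30) was lost without knockout progesterone library 5 (−1.18 ± 0.32, 0.0701), without knockout progesterone library 6 (−1.18 ± 0.32, 0.0518), without floxed progesterone library 1 (−1.09 ± 0.31, 0.0577), without floxed progesterone library 9 (−1.21 ± 0.32, 0.0576), with a pseudocount of 0.1 (−1.22 ± 0.53, 0.281), without the oviduct-bearing libraries (−1.23 ± 0.34, 0.0711) or without the 5 libraries (−1.30 ± 0.38, 0.117). The call of Sesn2 (−1.10 ± 0.21) was lost without the 5 libraries (−1.09 ± 0.27, 0.0526).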

How the results depend on the processing

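Tests on the linear scale, without genes that have a value below 0, in the vehicle-only batch alone, without the libraries with oviduct or squamous markers, and with other-tissue scores or a length slope as covariates were chosen only after the data were seen. Counts of called genes kept within 1.5 times of the main count under both other pseudocounts, without the filter, with both other scalings, without trend and robust, in the mixed batch alone, without genes that have a value below 0, on the linear scale and with either kind of covariate. Of 16323 values of named genes under alternatives, 24 changed sign, none of them in a called result. Calls were lost more often. Of 373 named results 366 were called. With the replicate block 151 lost the call, without the 5 libraries 72, in the mixed batch alone 55 and with only the groups compared in the fit 50. Over all the fits with 1 library left out, 420 values lost it. No value came from fitting only the contrast's groups for the difference in response, and the vehicle-only batch gives the vehicle contrast alone. Depth limits genes with few reads most, and the table gives no counts with which to test that. The cause was not tested for the changes below unless fewer genes or samples entered by construction.

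For the genotype effect under vehicle the filter at 5 RPKM gave 2293 genes, from fewer genes tested, weights per library 6500, and the vehicle-only batch 1085, from fewer samples. After progesterone weights gave 7123. For the response in floxed uteri weights gave 6276, leaving out the oviduct-bearing libraries 1924 and leaving out all 5 libraries 2064. In knockouts the fit without a batch term gave 1909, the fit of its own groups 678, weights 5965, leaving out the squamous-marker libraries 687 and 398 were called without all 5 libraries. For the difference in response the filter at 5 RPKM gave 137 higher and 99 lower, 2.4e+02 in all to 2 digits, weights 4122 and 213 were called without all 5 libraries. The weights did not converge fully. The slope across genotypes was 0.899 with genes called in knockouts.

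With each library left out in turn the counts ranged from 3101 to 3822 under vehicle, 2151 to 3245 between genotypes after progesterone, 2401 to 4101 in floxed uteri, 881 to 1339 in knockouts and 210 to 716 for the difference, where the lowest came without knockout progesterone library 5 and the highest without floxed vehicle library 12. Lists passing with an estimated correlation numbered 2, 1, 1, 1 and 0 in that order, and fry passed 0 for the difference.

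The replicate block left 7 residual degrees of freedom. The residuals of 9 same-number pairs correlated from −0.16 to 0.639, 5 of them above 0.1. Pairs with different numbers were not compared, so these values do not settle whether the numbers pair the samples. With the replicate block 822 genes were called between genotypes after progesterone, 162 for progesterone in knockouts and 26 for the difference, where 11 lists passed. The replicate block gave Esr1 under vehicle −0.007.

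Log2 fold changes near 0 changed sign. That of Esr1 under vehicle was −0.012 without knockout vehicle library 9, −0.001 without floxed vehicle library 3, −0.108 in the vehicle-only batch, −0.004 without oviduct-bearing libraries, −0.012 without squamous-marker ones, −0.036 without all 5 and −0.000 with tissue scores. With each library left out it lay between −0.012 and 0.048. That of Ctcf after progesterone in floxed uteri was 0.027 in the mixed batch, 0.009 without a batch term, 0.027 in its own groups, 0.050 with median-ratio scaling, 0.004 with suffixed libraries averaged, 0.019 with the length slope, and −0.039 to 0.016 over libraries left out. On the linear scale it was 0.098 RPKM.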

Other observations

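No test in this part was chosen after its result was seen. Hox genes moved in both directions under vehicle. Of 30 Hox genes 5 were higher and 4 lower (5 were higher and 4 lower adjusted over the list alone, camera adjusted p = 0.885) in knockouts. Hoxd3 changed by 0.83 ± 0.07, adjusted p = 6.37e-09, Hoxb9 by 0.53 ± 0.07, adjusted p = 1.77e-06 and Hoxd8 by 0.40 ± 0.06, adjusted p = 1.48e-05, and the median over the list was −0.07, its mean −0.01 and the direction of its camera test upward. After progesterone 7 were higher and 1 lower (8 were higher and 2 lower adjusted over the list alone, camera adjusted p = 0.323), with Hoxd8 at 0.74 ± 0.08, adjusted p = 9.89e-07. Of 14 loop factors 2 were higher and 1 lower (2 were higher and 1 lower adjusted over the list alone, camera adjusted p = 0.885) under vehicle, Ctcf itself among the lower. The median over the loop factors was 0.04 and their mean −0.03, with camera's direction upward and fry's downward. The cohesin gene Stag1 changed by 0.47 ± 0.05, adjusted p = 1.47e-07 under vehicle and by 0.59 ± 0.07, adjusted p = 1.5e-06 after progesterone. Of 27 imprinted genes 6 were higher and 2 lower (7 were higher and 3 lower adjusted over the list alone, camera adjusted p = 0.385) under vehicle, Igf2 among the higher. Of 31 WNT genes 10 were higher and 9 lower (12 were higher and 12 lower adjusted over the list alone, camera adjusted p = 0.856), with the WNT inhibitor gene Dkk3 at 1.11 ± 0.12, adjusted p = 2.35e-07 and Wnt11 at −2.42 ± 0.26, adjusted p = 2.58e-07. Of 20 epithelial markers 4 were higher and 11 lower (5 were higher and 11 lower adjusted over the list alone, camera adjusted p = 0.0772), with the protease gene St14 at 0.73 ± 0.09, adjusted p = 2.94e-06 and Cldn3 at −0.90 ± 0.14, adjusted p = 4.52e-05.

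Of 17 immediate early genes 5 were higher and none lower (5 were higher and none lower adjusted over the list alone, camera adjusted p = 0.0681) under vehicle, with Egr3 at 0.75 ± 0.14, adjusted p = 0.00021. After progesterone in floxed uteri 3 rose and 2 fell (4 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.226), with Egr1 at −1.14 ± 0.20, adjusted p = 0.000197 and the phosphatase gene Dusp1 at 0.89 ± 0.18, adjusted p = 0.000872. Of 22 endometrial cancer genes 1 was higher and 4 lower (1 was higher and 4 lower adjusted over the list alone, camera adjusted p = 0.559) under vehicle, Ctcf among the lower, with a median of 0.01, a mean of −0.09 and both test directions downward. Of 5 genes listed for the ovary 1 was higher and 1 lower (1 was higher and 2 lower adjusted over the list alone, camera adjusted p = 0.979) under vehicle. The median of that list was −0.20 and its mean 0.01, with camera's direction downward and fry's upward. The steroid synthesis gene Cyp11a1, in that list, changed by 1.23 ± 0.10, adjusted p = 4.19e-09 under vehicle and 1.18 ± 0.14, adjusted p = 2.48e-06 after progesterone. Of 7 squamous markers 1 was higher and 1 lower (1 was higher and 1 lower adjusted over the list alone, camera adjusted p = 0.62) under vehicle, with the cornified envelope gene Lor at 2.69 ± 0.27, adjusted p = 1.09e-07. No member of the oviduct (7 tested, camera adjusted p = 0.414), adipose (12, 0.648), nerve (7, 0.648) or red blood cell (5, 0.885) list was called by limma under vehicle, over all genes or adjusted over the list alone, and 1, 0, 0 and 0 of them in that order had an unadjusted p under 0.05.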
